A study of Mus musculus with 12 samples.

How the data were processed

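Gene expression was measured by RNA sequencing in 12 libraries of mouse pancreatic tumour cells, 3 for each of 4 genotype labels: WT, EgfrKO, Klf5KO and Smad4KO. Per the labels' protocols, cells named 6649c2 were grown as subcutaneous tumours in C57BL/6 mice and sorted from those tumours, RNA was extracted with a Qiagen RNeasy micro kit, and a company, Novogene, did the steps that followed. The gate used for sorting is not given in the sources used here.

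The authors deposited 1 table of TPM per gene, the share of a library's transcripts after allowing for their lengths, with 1 column for each library. Per the submitters' processing notes, Salmon and the mm10 build were used, and the version of Salmon, the transcript annotation and the way transcripts were summed to genes are not given in the sources used here. The columns of deposited TPM all have the same sum over 24493 gene symbols, so a value is a share of a library and not an amount. TPM keeps no read depth, so the depth of each library is unknown, no counting interval or detection limit is given, and a gene at 0 is described only as listed at 0. Of the symbols, 23852 (97.4%) matched a gene of the RefSeq annotation of GRCm38.p6, the assembly that mm10 represents, which was used for coordinates.

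Columns were matched to samples by name and samples to genotypes by their labels. Values were transformed to log2(TPM + 1), and the 13662 genes with TPM of at least 1 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3. A single model with 4 genotype means was fitted to all 12 libraries, with eBayes and a trend in the spread, and 6 contrasts were taken from it. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method within each contrast, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values, and are given with their standard errors (SE). Means of TPM are given with standard deviations (SD). For the targeted genes a two-sided exact permutation test was added, whose smallest possible p with 3 libraries against 3 is 0.1. The labels do not say whether the replicates came from separate animals or tumours, so p-values measure the spread between these samples, which may be technical.

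Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The 27 lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, and the 81 tests against WT were adjusted together. Camera compares a list with the other genes, so its direction can differ from the sign of the list's median where all genes shift. Camera was repeated with an estimated correlation, and fry was run as another test, which asks whether the genes of a list move one way on balance. No list passed the threshold with an estimated correlation in any of the 3 contrasts against WT, with smallest adjusted p of 0.184, 0.140 and 0.140 for EgfrKO, Klf5KO and Smad4KO. At an unadjusted p under 0.05 camera called 6, 5 and 5 lists there, and fry called 20, 20 and 19 after adjustment. Camera on the contrasts between knockouts, with all libraries and without each in turn, was added after the data were seen.

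The genes named are Egfr, Klf5, Smad4, Cxcl1, Csf3 and Cxcl10, and in each contrast against WT the 8 with the largest increase and the 8 with the largest decrease among genes past the threshold whose groups did not overlap, with a mean TPM of at least 5 and a named symbol. Symbols of unnamed gene models were left out. To these were added up to 3 members of each called list with the smallest adjusted p, 4 genes per direction in each contrast between knockouts, 5 per direction changed alike in the 3 knockouts, and the 2 most abundant members of each cell type list. Values of some genes that the rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

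The alternatives were another pseudocount, no filter or a stricter filter on low values, median-of-ratios scaling, quantile normalization, leaving out the 20 most abundant genes, other treatments of the spread, a fit of the 2 groups compared, the replicate number as a block, a leukocyte or fibroblast list as a covariate, a minimum fold change, and leaving out each library in turn. Leaving out small RNA models, leaving out ribosomal protein genes and a macrophage list as a covariate were added after the data were seen. The fitting functions were tested on simulated data made from the means and spreads of the 13662 genes. With 200 genes changed in the simulated EgfrKO against WT contrast, 62.7% of changes of 0.5 on the log2 scale, 91.0% of changes of 1 and 100% of changes of 2 were recovered, with 10 false calls among 13438 unchanged genes. In the simulated Klf5KO contrast 55.2%, 89.6% and 92.4% were recovered with 13 false calls, and in the simulated Smad4KO contrast 58.2%, 80.6% and 98.5% with 8. A list shifted on purpose was called by camera in each, and 1 other list was called in the simulated EgfrKO contrast. The simulated genes were drawn independently of each other. They therefore do not show how often camera calls lists wrongly where genes are correlated.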

Results

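The series compared WT mouse pancreatic tumour cells with cells of the same name labelled as a knockout of 1 of 3 genes. The labels do not say whether a knockout is 1 clone or a pool of cells. Differences between clones therefore cannot be told apart from effects of the targeted gene. Egfr encodes the epidermal growth factor receptor, Klf5 a zinc finger transcription factor of epithelial cells, and Smad4 the shared mediator of TGF-beta and BMP signalling. RNA was sequenced from 3 libraries of each genotype label, 12 in all, of cells sorted from subcutaneous pancreatic tumours in mice. Between 12592 and 13141 genes reached a TPM of 1 in each library. Correlations of log2(TPM + 1) across genes were 0.980 to 0.988 between libraries of the same genotype and 0.917 to 0.966 between libraries of different genotypes, and genes are not independent replicates. The microRNA model Mir6236, an annotated span of 123 bp on chromosome 9 (110281287 to 110281409), took 3.87% to 8.93% of the TPM of a library, and reads on so short a model are uncertain.

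In TPM, Egfr and Smad4 transcripts were lowest in the libraries labelled for their knockout, and Klf5 transcripts were not. Egfr (chromosome 11, 16752203 to 16913907 in GRCm38.p6) was 13.1 ± 0.85 TPM (SD, n = 3) in WT and 4.29 ± 0.76 in EgfrKO, 32.7% of WT. Smad4 (chromosome 18, 73634790 to 73703791) was 75.5 ± 4.45 TPM in WT and 30.7 ± 2.39 in Smad4KO, 40.7% of WT. Klf5 (chromosome 14, 99298691 to 99313412) was 112 ± 16.8 TPM in WT and 93.8 ± 6.35 in Klf5KO, 83.6% of WT, with 84.9 ± 3.55 TPM in EgfrKO and 125 ± 10.3 in Smad4KO. Smad4 was 64.0 ± 2.39 TPM in EgfrKO and 95.8 ± 5.48 in Klf5KO. Exact permutation p was 0.1, the smallest possible, for Egfr in EgfrKO and for Smad4 in Smad4KO, and 0.2 for Klf5 in Klf5KO.

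The limma test gave adjusted p = 5.9e-05 for Egfr in EgfrKO, 6.9e-08 for Smad4 in Smad4KO and 0.041 for Klf5 in Klf5KO, where the log2 fold change was -0.25 ± 0.10 (SE). After median-of-ratios scaling the log2 fold change of Klf5 was -0.57 in Klf5KO (adjusted p = 0.00044) and -0.51 in EgfrKO (0.0013). The call on Klf5 in Klf5KO as measured was lost without WT replicate 2, WT replicate 3, Klf5KO replicate 2 or Klf5KO replicate 3, with adjusted p of 0.0659, 0.182, 0.128 and 0.0843, with a replicate block (0.0556), no filter on low values (0.0650), no trend in the spread (0.0592), or the leukocyte (0.675), fibroblast (0.894) or macrophage list (0.105) as a covariate. Gene-level TPM can still count the transcripts of an edited gene, so these values do not check the Klf5KO label. Those libraries are called Klf5KO-labelled or Klf5KO below, and where knockouts are counted they are included by label only. Egfr also fell in the Klf5KO-labelled libraries, to 6.93 ± 1.45 TPM, and in Smad4KO, to 7.95 ± 1.88 TPM, with adjusted p of 0.00094 and 0.0060. The former call was lost with the leukocyte list (0.0583) or the fibroblast list (0.176) as a covariate. Its log2 fold change of -0.85 became -0.59 with the leukocyte list and -0.96 with the fibroblast list, so the latter did not make the fall smaller. Smad4 fell in EgfrKO (adjusted p = 0.017), a call lost without WT replicate 3 (0.0697) or EgfrKO replicate 3 (0.0555) or with the leukocyte covariate (0.166). Smad4 rose in Klf5KO (adjusted p = 0.00095), where the log2 fold change of 0.34 became 0.02 after median-of-ratios scaling (0.795). That call was also lost with quantile normalization, where the fold change was 0.11 (adjusted p = 0.114). With the fibroblast covariate it was lost too (adjusted p = 0.281), while the fold change stayed at 0.30. Klf5 was not called in Smad4KO (adjusted p = 0.196), and without WT replicate 3 it was (0.0223).

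**Figure D1:**
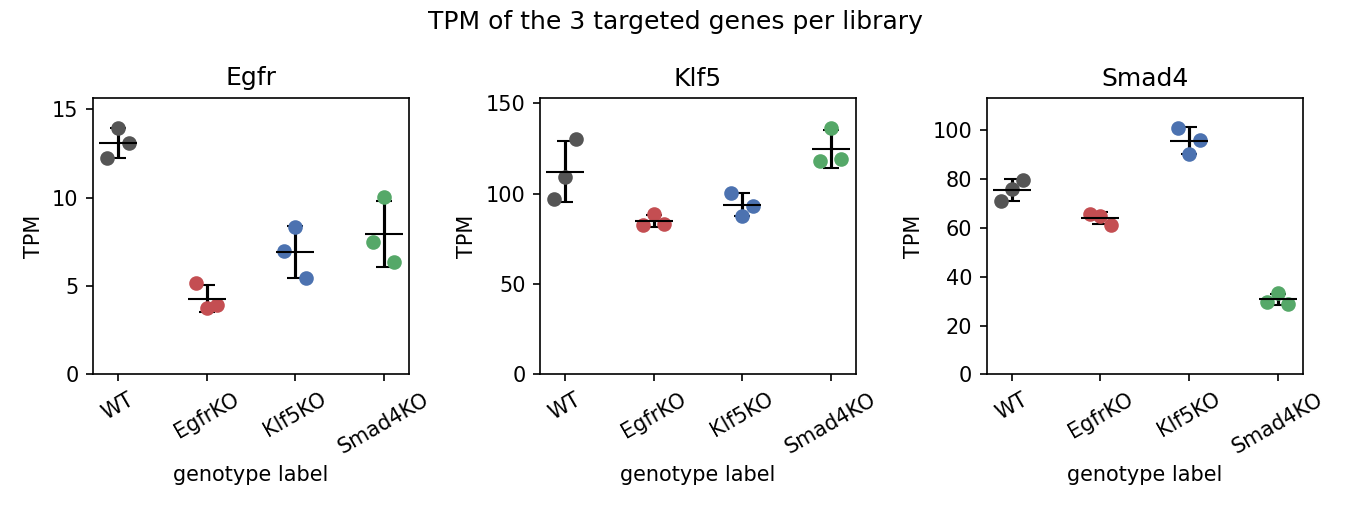
TPM of Egfr, Klf5 and Smad4 (vertical axes, linear, from 0) in each library by genotype label (horizontal axes), with points for the 3 libraries, a horizontal line for the mean and error bars for the SD. Egfr averaged 13.1 TPM in WT and 4.29 in EgfrKO, Smad4 75.5 in WT and 30.7 in Smad4KO, and Klf5 112 in WT and 93.8 in Klf5KO.

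The fold changes of all genes were not centred on 0. Their median on the log2 scale was 0.14 in EgfrKO, 0.31 in the Klf5KO-labelled libraries and 0.10 in Smad4KO against WT, and median-of-ratios scaling moved them by 0.12, 0.31 and 0.09. Ribosomal protein genes took 12.9% to 14.5% of TPM in the Klf5KO-labelled libraries and 18.5% to 20.9% in the others. Camera compares a list with the other genes and so is relative to this shift, and the plot of list medians shows them after scaling. Counts of list members are over all genes tested, and the count adjusted over the list alone was the same except where it is given.

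The first comparison asks which genes differed between EgfrKO and WT tumour cells. Antigen presentation and interferon genes rose, and ERK feedback genes, myeloid cytokines and hypoxia genes fell. All 7 MHC class II genes tested rose, with a median log2 fold change of 3.01 (2.89 after scaling), among them Cd74, the invariant chain, from 210.0 ± 77.2 to 1669 ± 69.1 TPM and H2-Aa from 48.0 ± 18.9 to 448 ± 7.54 TPM. All 13 MHC class I genes and 25 of 26 interferon-stimulated genes rose, with Gbp2, an interferon-induced GTPase, at 5.6 times its WT level. The chemokines Cxcl9 and Ccl5, which attract T cells, were 11.8 and 12.9 times their WT level, while the list of 7 such chemokines, of which 4 rose, was not called by camera (adjusted p = 0.150) and was called higher by fry, a test against no change (9.0e-05). Camera called these lists higher at adjusted p of 4.6e-06 for MHC class II, 6.9e-09 for MHC class I and 3.5e-10 for interferon-stimulated genes, and with an estimated correlation adjusted p was 0.273, 0.273 and 0.276.

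Of 20 ERK feedback and EGFR output genes, 12 fell (13 adjusted over the list alone) and 1 rose in EgfrKO. Dusp5 and Dusp4, phosphatases that act on MAP kinases, were 0.358 and 0.363 times WT. Of 8 ERBB ligand and receptor genes 5 fell, including Areg, from 80.2 ± 7.54 to 27.1 ± 1.66 TPM, and Hbegf, from 273 ± 17.4 to 137 ± 3.57 TPM. Of 15 TGF-beta and SMAD4 target genes 11 fell. Camera called the 3 lists lower at adjusted p of 2.4e-07, 0.00063 and 5.5e-07, and with an estimated correlation adjusted p was 0.214, 0.229 and 0.184. Of 15 myeloid-attracting cytokine genes 11 fell (12 adjusted over the list alone), with Csf2 from 44.5 ± 16.3 to 6.33 ± 0.33 TPM and Cxcl1 from 121 ± 41.0 to 31.3 ± 2.24 TPM. Of 19 hypoxia and glycolysis genes 17 fell, with Car9, a carbonic anhydrase induced by hypoxia, at 0.370 times WT. Camera gave adjusted p of 8.4e-09 for the cytokines and 1.5e-12 for hypoxia and glycolysis, and with an estimated correlation adjusted p was 0.20 and 0.254.

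Of 18 classical and gastric-like genes 12 rose and 1 fell in EgfrKO, with Tff1, a gastric trefoil peptide, from 294 ± 71.2 to 1249 ± 26.1 TPM (adjusted p = 0.0018, and 0.284 with an estimated correlation). Of 24 cell cycle genes 20 rose, with a median of 0.39 that became 0.27 after scaling (adjusted p = 0.00014, and 0.435 with an estimated correlation). Of 16 mesenchymal genes 5 fell and 2 rose, with Fn1, fibronectin, at 0.393 times WT, and of 7 squamous and basal-like genes 3 fell, with Sprr1a at 0.346 times WT (adjusted p = 0.0065 for each list, and 0.254 and 0.228 with an estimated correlation). Of 15 epithelial identity genes 8 rose and 3 fell (4 adjusted over the list alone), and Epcam, a surface marker of epithelial cells, fell from 13.5 ± 1.84 to 1.30 ± 0.09 TPM. Camera did not call the list (adjusted p = 0.471), and fry called it higher (0.0138). Camera did not call BMP targets (2 rose and 1 fell of 5, adjusted p = 0.636), cholesterol synthesis (3 and 4 of 18, 0.0641) or unfolded protein stress genes, where 5 rose (6 adjusted over the list alone) and 4 fell of 12, with a median of 0.13 against a camera direction of down (0.757). Of these 3, fry called the last, as higher (0.0304). The genes with the largest decrease included Mgp, matrix Gla protein, from 184 ± 19.2 to 7.38 ± 1.35 TPM, and Reg3b, whose reads may be shared with Reg3g.

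Immediate-early and dissociation stress genes also fell in EgfrKO, 12 of 14 (14 adjusted over the list alone), with the heat shock gene Hspa1a at 0.268 times WT (adjusted p = 2.2e-09, and 0.254 with an estimated correlation). Markers of other cell types moved as well. Of 11 T and NK cell genes 6 rose (7 adjusted over the list alone), and of 5 endothelial genes 4 rose. The T and NK cell genes had low values, with Nkg7 at 2.41 ± 1.19 TPM in EgfrKO and 0.16 ± 0.19 in WT. Camera gave adjusted p of 0.037 and 0.011 for T and NK cells and endothelial cells, and with an estimated correlation adjusted p was 0.276 and 0.214. The T and NK cell call was lost without WT replicate 3 (0.0631) or EgfrKO replicate 3 (0.0550), and with the leukocyte list (0.122) or the macrophage list (0.0533) as a covariate. Retnla, a gene of alternatively activated macrophages, rose from 28.3 ± 13.7 to 420 ± 23.7 TPM. In all, 4277 genes were higher and 1643 lower, 72.2% higher, and after median-of-ratios scaling 2788 were higher and 2721 lower, 50.6% higher. Groups did not overlap for 56.0% of genes before scaling, where chance with no shift of all genes gives 10%.

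The next comparison asks which genes differed between the Klf5KO-labelled libraries and WT. Antigen presentation genes rose and epithelial, squamous, cytokine and hypoxia genes fell. All 7 MHC class II genes rose, with a median of 3.65 (3.32 after scaling) and Cd74 at 2884 ± 224 TPM against 210.0 ± 77.2 in WT. All 13 MHC class I genes and 23 of 26 interferon-stimulated genes rose, with 17 past the threshold after scaling. Camera gave adjusted p of 0.00039, 9.7e-06 and 0.00074, and with an estimated correlation adjusted p was 0.363, 0.369 and 0.552. The list of T cell-attracting chemokines, with 5 of 7 up and 2 down, was called higher by fry (adjusted p = 1.5e-05) and not by camera (0.313), and Cxcl9 was 18.7 times WT. Adgrg7, an adhesion receptor, rose from 0.87 ± 0.35 to 57.3 ± 9.19 TPM.

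Of 15 epithelial identity genes 9 fell (10 adjusted over the list alone) and 2 rose in the Klf5KO-labelled libraries. Krt7, a keratin of ductal cells, fell from 61.6 ± 3.15 to 5.07 ± 1.34 TPM and Epcam from 13.5 ± 1.84 to 0.54 ± 0.20 TPM. Of 7 squamous and basal-like genes 6 fell, with Lamb3, a laminin chain, at 0.156 times WT. Of 18 classical and gastric-like genes 7 fell and 5 rose, with Tff2 at 0.218 times WT. Camera called these lists lower at adjusted p of 8.8e-07, 1.2e-06 and 0.00093, and with an estimated correlation adjusted p was 0.229, 0.140 and 0.276. The call on the classical and gastric-like list was lost after median-of-ratios scaling, at 0.0704, and after quantile normalization, at 0.0763. Its median of -0.15 was -0.26 after either. Of 13 fibroblast genes 12 rose, with 8 past the threshold after scaling, with Col1a1, a collagen chain, from 29.2 ± 12.1 to 164 ± 67.0 TPM, and of 16 mesenchymal genes 12 rose and 2 fell. Camera did not call these 2 lists (adjusted p = 0.085 and 0.173), and fry called both higher (0.00035 and 3.4e-06).

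Of 15 myeloid-attracting cytokine genes 12 fell in the Klf5KO-labelled libraries. Cxcl2, a neutrophil chemokine, fell from 102 ± 30.2 to 13.1 ± 3.49 TPM, and Csf1, a macrophage growth factor, rose from 6.95 ± 0.05 to 17.6 ± 1.02 TPM. Of 19 hypoxia and glycolysis genes 16 fell, with Vegfa at 0.364 times WT, and of 18 cholesterol synthesis genes 9 fell and 1 rose, with Insig1 at 0.620 times WT. After scaling all 19 hypoxia and glycolysis genes fell, and 16 cholesterol synthesis genes fell and none rose. Camera gave adjusted p of 5.4e-09, 4.0e-14 and 2.9e-06 for the 3 lists, and with an estimated correlation adjusted p was 0.20, 0.229 and 0.389. Fry did not call the cholesterol list (0.0850). Cell cycle genes rose in 22 of 24, with a median of 0.56 that became 0.25 after scaling, where 12 rose and 2 fell (adjusted p = 0.0040, and 0.552 with an estimated correlation). Of 8 ERBB genes 5 fell and 3 rose, with Erbb3 at 0.239 and Erbb2 at 1.63 times WT, and of 5 BMP target genes 3 fell and 1 rose (2 adjusted over the list alone), with Id1 at 0.504 times WT. These calls, at adjusted p of 0.0065 and 0.039 and with an estimated correlation 0.273 for both, were lost after median-of-ratios scaling, at 0.0677 and 0.178, and after quantile normalization, at 0.0589 and 0.152. The list medians of -0.31 and -0.42 did not shrink, at -0.63 and -0.74 after median-of-ratios scaling and -0.48 and -0.52 after quantile normalization. The BMP call was also lost without WT replicate 3 (0.0618) or Klf5KO replicate 3 (0.0558), and with the leukocyte list (0.106) or the macrophage list (0.0564) as a covariate. With the fibroblast list as a covariate the calls on Cxcl2, Vegfa and Erbb2 were lost, where log2 fold changes of -2.86, -1.48 and 0.68 became -1.55, -0.68 and 0.31 (adjusted p = 0.0586, 0.129 and 0.165).

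ERK feedback genes went both ways in the Klf5KO-labelled libraries, 10 up (11 adjusted over the list alone) and 7 down, and after scaling 4 up and 8 down. TGF-beta and SMAD4 targets turned from 6 up and 3 down to 2 up and 9 down. Neither list was called by camera (adjusted p = 0.064 and 0.051) or fry (0.431 and 0.555), and for both the median was above 0 while the mean was below 0 and camera's direction was down. Unfolded protein stress genes, 8 up and 2 down of 12, became 4 up and 5 down after scaling, and were called higher by fry (adjusted p = 0.00035) and not by camera (0.892). Of 14 immediate-early and dissociation stress genes 12 fell and 1 rose, with Atf3, a stress-induced transcription factor, at 0.174 times WT (adjusted p = 1.6e-10, and 0.229 with an estimated correlation). Of 7 general leukocyte genes 6 rose, with 2 past the threshold after scaling (adjusted p = 0.486). The largest decreases included Reg3b, from 76.4 ± 21.2 to 0.87 ± 0.30 TPM, and S100g, a calcium-binding protein, at 0.0328 times WT. In all, 7536 genes were higher and 1518 lower, 83.2% higher, and after median-of-ratios scaling 3695 were higher and 3477 lower, 51.5% higher. With the fibroblast list as a covariate 889 were higher and 348 lower. The mean of that list was 3.76 to 4.35 in these libraries and 2.24 to 3.04 in WT, so the covariate cannot be fully told apart from the label. Groups did not overlap for 69.0% of genes before scaling, where chance with no shift of all genes gives 10%. The shift of all genes, a median of 0.31, may add to this share.

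The third comparison asks which genes differed between Smad4KO and WT tumour cells. Antigen presentation, epithelial and gastric-like genes rose, and TGF-beta target, mesenchymal, cytokine and ERK feedback genes fell. All 7 MHC class II genes, all 13 MHC class I genes and 24 of 26 interferon-stimulated genes rose (25 of the last adjusted over the list alone), with MHC class II at a median of 3.42 and Cd74 at 2589 ± 319 TPM. Camera gave adjusted p of 1.3e-05, 1.7e-07 and 1.4e-07, and with an estimated correlation adjusted p was 0.276, 0.284 and 0.363. Of 15 epithelial identity genes 14 rose and only Sox9 fell, a member chosen after its values were seen. Muc1, a membrane mucin, rose from 38.2 ± 7.69 to 193 ± 3.66 TPM. Of 18 classical and gastric-like genes 15 rose, with Tff1 from 294 ± 71.2 to 2428 ± 61.2 TPM. Adjusted p was 3.0e-05 and 2.7e-06 for the 2 lists, and with an estimated correlation 0.263 and 0.228.

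Of 15 TGF-beta and SMAD4 target genes 13 fell and 2 rose in Smad4KO, with Tgfb1 at 0.540 times WT. Of 16 mesenchymal genes 13 fell and none rose, with Tnc, tenascin C, at 0.314 times WT. Of 20 ERK feedback genes 12 fell and 1 rose, with Etv4 at 0.542 times WT, and of 8 ERBB genes 6 fell and 2 rose, with Hbegf at 0.415 and Erbb3 at 2.45 times WT. Camera gave adjusted p of 7.2e-07, 1.7e-07, 2.0e-06 and 0.0065 for the 4 lists, and with an estimated correlation adjusted p was 0.184, 0.140, 0.228 and 0.273. Of 15 myeloid-attracting cytokine genes 12 fell and none rose (2 rose adjusted over the list alone), with Cxcl2 at 0.179 times WT. Csf3 was 1.46 ± 0.38 TPM in WT and 0.02 ± 0.03 in Smad4KO. Of 19 hypoxia and glycolysis genes 15 fell and 1 rose, with Eno1, enolase 1, at 0.669 times WT. Car9, which fell in EgfrKO, was 231 to 235 TPM in Smad4KO and 190 to 212 in WT. It was chosen here after its values were seen. After median-of-ratios scaling 16 of the 19 fell and 0 rose. Camera adjusted p was 4.8e-06 for the cytokines and 3.7e-07 for hypoxia and glycolysis, and with an estimated correlation 0.229 and 0.363.

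Cell cycle genes rose in 16 of 24 in Smad4KO (19 adjusted over the list alone) and 1 fell (adjusted p = 0.012, and 0.620 with an estimated correlation), with Mcm7 at 1.25 times WT. Lists not called by camera were BMP targets (2 rose and 2 fell of 5, adjusted p = 0.915), squamous genes (1 and 2 of 7, 0.140), T cell-attracting chemokines (5 and 2 of 7, 0.138), cholesterol synthesis (4 and 4 of 18, 0.605, with a median of 0.05 and a mean of -0.01) and unfolded protein stress (5 and 2 of 12, 3 fell adjusted over the list alone, 0.646). Of these, fry called BMP targets, chemokines and unfolded protein stress higher (0.040, 6.0e-05 and 0.0014) and squamous genes lower (0.00775), and did not call cholesterol synthesis (0.897). Of 14 immediate-early and dissociation stress genes 12 fell (13 fell and 1 rose adjusted over the list alone), with Hspa1b, which shares reads with its near-identical copy Hspa1a, at 0.272 times WT (adjusted p = 2.4e-07, and 0.276 with an estimated correlation). The largest increases included Pigr, the receptor that carries immunoglobulins across epithelia, from 0.38 ± 0.22 to 53.4 ± 0.82 TPM, Sftpd, surfactant protein D, from 2.35 ± 1.09 to 103 ± 4.71 TPM, and Gpx2, a glutathione peroxidase, from 5.31 ± 1.64 to 113 ± 2.86 TPM. The largest decreases included Ccbe1, from 11.6 ± 2.17 to 0.27 ± 0.02 TPM, and Mcpt8, at 0.112 times WT.

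Camera called macrophage and fibroblast genes lower in Smad4KO (adjusted p = 0.024 and 0.034, and 0.646 and 0.552 with an estimated correlation), with 2 of 12 and 2 of 13 members past the threshold (none of the macrophage genes adjusted over the list alone). Lyz2 was 206 ± 119 TPM in Smad4KO and 438 ± 216 in WT (adjusted p = 0.049), a call lost without WT replicate 1 (0.0567), 2 (0.183) or 3 (0.0512) or Smad4KO replicate 2 (0.165), and with a replicate block (0.0786), quantile normalization (0.0502), no filter on low values (0.0888), no trend in the spread (0.0640), a robust spread (0.102) or array weights (0.0561). Smad4KO replicate 2 stood apart, with the complement gene C1qa at 29.9 TPM against 149 and 162 in the other Smad4KO libraries, and without it adjusted p for the macrophage list was 0.410. With the leukocyte list as a covariate it was 0.251. That call was also lost without WT replicate 2 (0.0991), and the fibroblast call without WT replicate 1 (0.181) or Smad4KO replicate 1 (0.0523). Both were lost after median-of-ratios scaling, at 0.0930 and 0.0854, and after quantile normalization, at 0.117 and 0.0838, and fry called neither (0.240 and 0.107). The macrophage and fibroblast medians of -0.66 and -0.48 did not shrink, at -0.76 and -0.56 after median-of-ratios scaling and -0.75 and -0.62 after quantile normalization. In all, 4400 genes were higher and 2381 lower, 64.9% higher, and after median-of-ratios scaling 3514 were higher and 3335 lower, 51.3% higher. Groups did not overlap for 59.1% of genes before scaling, where chance with no shift of all genes gives 10%.

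**Figure D2:**
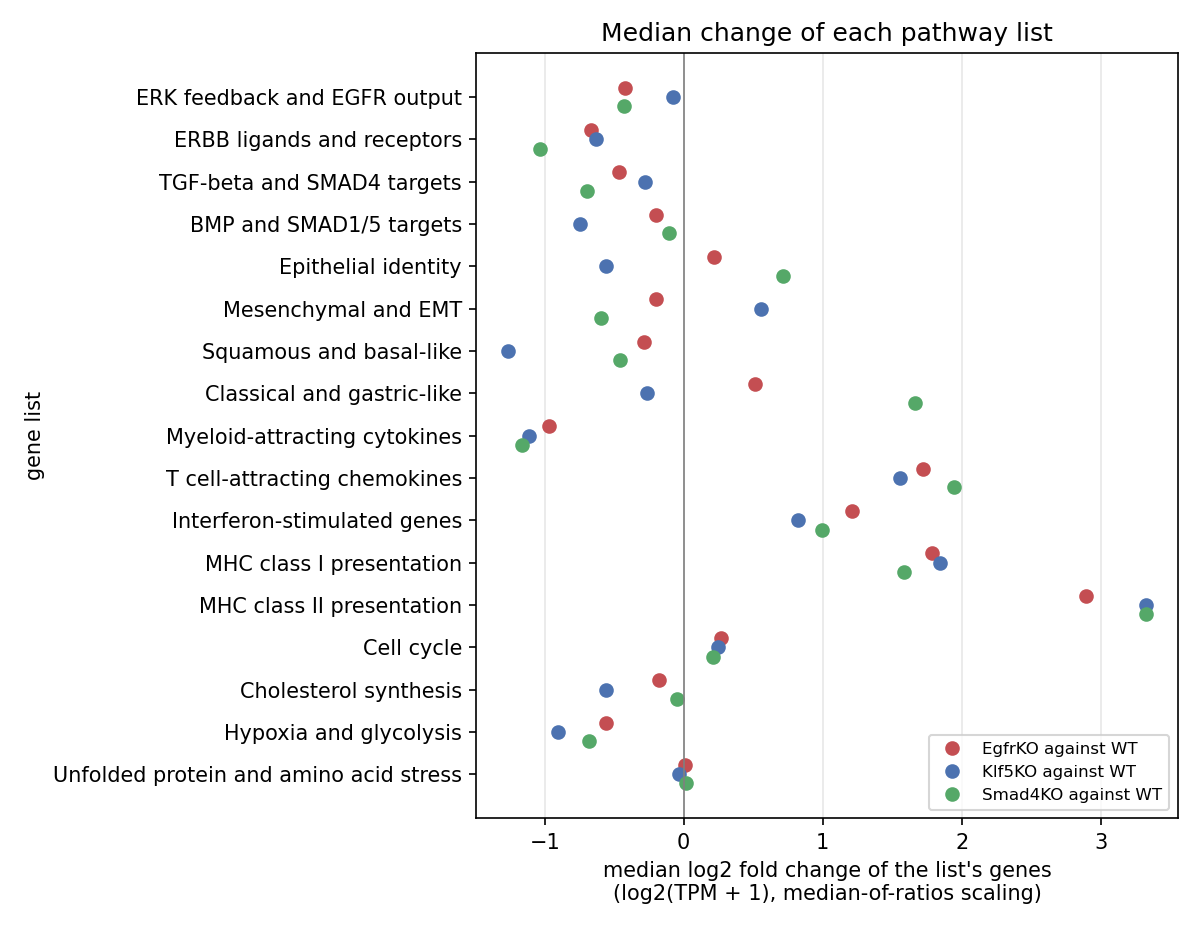
Median log2 fold change against WT (horizontal axis, log2(TPM + 1) after median-of-ratios scaling) of the tested genes of each pathway list (vertical axis), with 1 point for each knockout label. The MHC class II list lies at 2.89, 3.32 and 3.32 in EgfrKO, Klf5KO and Smad4KO, and the epithelial identity list at 0.22, -0.56 and 0.71.

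Across the 3 knockouts, 1945 genes were higher and 444 lower than WT in all 3. Among the higher were H2-T23, a nonclassical MHC class I gene, Casp1, an inflammasome protease, and Txnip, which binds thioredoxin, at 2.71, 5.11 and 1.95 times WT in EgfrKO. Among the lower were Dusp5, Trib2 and Hspa1a, at 0.358, 0.213 and 0.268 times WT in EgfrKO. After median-of-ratios scaling 845 were higher and 998 lower in all 3. The 3 contrasts share the WT libraries. In simulations that redrew all 12 libraries, WT included, with no changed gene, 0 genes were shared in each direction on average. Such a simulation calls almost no gene in any contrast, so it sets no baseline for sharing through common controls. Independent lists of the same sizes would share 759.8 higher and 31.8 lower genes. Part of the excess over independent lists may come from the shared controls, which are too few to be split.

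The fold changes of EgfrKO and Smad4KO correlated across genes with r = 0.65, those of EgfrKO and the Klf5KO-labelled libraries with r = 0.52, and those of the Klf5KO-labelled libraries and Smad4KO with r = 0.24. Simulated unchanged groups gave 0.50 for each pair. That value follows from the shared WT libraries when no gene changes, so it sets no baseline for these correlations. Covariances were 0.211, 0.163 and 0.0948, against 0.0228 to 0.0229 in the simulation. A test of any difference between genotypes called 11298 of 13662 genes.

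The knockouts were compared with each other to find where they differ, and epithelial, gastric-like, mesenchymal and fibroblast genes were among those that differed. Between the Klf5KO-labelled libraries and Smad4KO, 8716 genes changed, with Dmbt1, a mucosal scavenger receptor, at 3.29 ± 1.54 and 610.2 ± 70.8 TPM and Rhox5, a homeobox gene, at 139 ± 15.9 and 5.86 ± 1.67 TPM. Of 18 classical and gastric-like genes 13 were lower and 2 higher in the Klf5KO-labelled libraries than in Smad4KO, of 15 epithelial genes 13 were lower (14 adjusted over the list alone) and 1 higher, and of 16 mesenchymal genes 15 were higher (camera adjusted p = 2.8e-07, 9.2e-09 and 7.5e-05, and 0.319 for each with an estimated correlation). Of 13 fibroblast genes 12 were higher (adjusted p = 0.014, and 0.927 with an estimated correlation). Of 7 squamous genes 3 were lower and 1 higher, and of 18 cholesterol synthesis genes 9 were lower (10 adjusted over the list alone) and 4 higher (adjusted p = 0.0186 and 0.00759, and 0.325 and 0.993 with an estimated correlation). After median-of-ratios scaling 6 squamous genes were lower and none higher, and 14 cholesterol synthesis genes were lower and 2 higher. The squamous median of -0.56 was -0.33 without Klf5KO replicate 1 and -0.94 without Klf5KO replicate 2, and the cholesterol median of -0.27 was -0.16 without Klf5KO replicate 2, with both lists still called.

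Between EgfrKO and the Klf5KO-labelled libraries 7535 genes changed, with Krt7 at 159 ± 6.32 and 5.07 ± 1.34 TPM and the collagen gene Col12a1 at 4.33 ± 0.42 and 38.3 ± 8.02 TPM. Of 18 classical and gastric-like genes 12 were higher (13 adjusted over the list alone) and 4 lower in EgfrKO, of 15 epithelial genes 9 were higher and 1 lower, and of 16 mesenchymal genes 13 were lower (1 was higher adjusted over the list alone, adjusted p = 1.3e-06, 3.9e-06 and 0.0013, and 0.319, 0.325 and 0.319 with an estimated correlation). Of 13 fibroblast genes 8 were lower in EgfrKO and none higher, with a median of -0.71, while camera did not call the list (adjusted p = 0.159, and 0.993 with an estimated correlation). Immediate-early and dissociation stress genes were higher in EgfrKO, 7 of 14 with 2 lower, as were squamous genes, 4 of 7 with 1 lower, cholesterol synthesis genes, 9 of 18 with 2 lower, and interferon-stimulated genes, 7 of 26 (5 adjusted over the list alone) with 1 lower (adjusted p = 0.0160, 0.0183, 0.00759 and 0.0324, and 0.993, 0.325, 0.993 and 0.993 with an estimated correlation). The stress call was lost without Klf5KO replicate 1 (0.0828), where the median of 0.25 was 0.12, and the median was 0.42 without Klf5KO replicate 2. The cholesterol call was lost without Klf5KO replicate 2 (0.0680), where the median of 0.22 was 0.12, and the interferon call without Klf5KO replicate 3 (0.0876). The interferon median of 0.02 was 0.03, -0.00035 and 0.05 without EgfrKO replicate 1, 2 and 3, and 0.04 and 0.07 without Klf5KO replicate 1 and 2.

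Between EgfrKO and Smad4KO 4531 genes changed, with Epcam at 1.30 ± 0.09 and 39.5 ± 2.38 TPM. Of 15 epithelial genes 10 were lower in EgfrKO and 1 higher (2 adjusted over the list alone), of 18 classical and gastric-like genes 10 were lower (11 lower and 1 higher adjusted over the list alone), and of 16 mesenchymal genes 9 were higher and 1 lower (camera adjusted p = 0.00035, 0.00054 and 0.0012, and 0.563, 0.521 and 0.319 with an estimated correlation). The epithelial median of -0.36 was -0.23 without EgfrKO replicate 3. ERK feedback and EGFR output genes were not lower in EgfrKO than in Smad4KO. Of the 20, 7 were higher and 1 lower (8 and 2 adjusted over the list alone), with a median of 0.05. Camera did not call this list (adjusted p = 0.380). Against the Klf5KO-labelled libraries 2 were higher and 12 lower in EgfrKO (3 and 14 adjusted over the list alone), and camera did not call it either (0.199). Macrophage genes were higher in EgfrKO than in Smad4KO, 6 of 12 (10 adjusted over the list alone), and so were 6 of 7 general leukocyte genes (7 adjusted over the list alone) and 6 of 13 fibroblast genes (8 adjusted over the list alone), with adjusted p of 0.010, 0.0186 and 0.010, and 0.993, 0.927 and 0.927 with an estimated correlation. The macrophage median of 1.34 was 0.63 without Smad4KO replicate 2, and the list was still called (adjusted p = 0.0267). With the leukocyte list as a covariate 1996 genes changed between EgfrKO and Smad4KO.

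The sorted cells held transcripts of other cell types in every group. Macrophage genes were the most abundant of these, with C1qa at 172 ± 60.2 TPM in WT, 265 ± 13.8 in EgfrKO, 239 ± 62.3 in the Klf5KO-labelled libraries and 114 ± 72.9 in Smad4KO. Haemoglobin Hba-a1, whose reads may be shared with Hba-a2, was 52.3 to 76.5 TPM on average in the 4 groups. T cell, B cell and dendritic cell genes had low values, with Cd3d between 2.44 and 2.78 TPM, Cd22 between 0.41 and 1.83 TPM and Itgax between 1.18 and 8.23 TPM on average. The other cell type lists were not called by camera, with adjusted p given in brackets in the order EgfrKO, Klf5KO and Smad4KO. Of them fry called dendritic cell (0.00052) and adipocyte and muscle genes (0.0318) higher in EgfrKO, general leukocyte (0.00886), T and NK cell (1.5e-05), dendritic cell (0.00019), fibroblast and endothelial genes in Klf5KO (0.00035 and 3.4e-06), and T and NK cell and endothelial genes in Smad4KO (0.00032 and 0.00023). Of 7 general leukocyte genes 3 rose and 1 fell in EgfrKO (5 rose adjusted over the list alone, adjusted p = 0.605), and 2 fell in Smad4KO (1 adjusted over the list alone, 0.121). Of 11 T and NK cell genes 8 rose in Klf5KO (0.168) and 6 in Smad4KO (0.0858). The 12 macrophage genes had medians of 0.67 in EgfrKO (0.658) and 0.58 in Klf5KO (0.546, with camera's direction down). Of 7 neutrophil genes 1 rose in each group and 2, 2 and 1 fell (0.555, 0.471 and 0.425). Of 4 dendritic cell genes 2 rose in EgfrKO (0.217) and 2 in Klf5KO (3 adjusted over the list alone, 0.538), and the list had a median of 0.02 in Smad4KO (0.732). Of 5 endothelial genes 3 rose in Klf5KO (0.258) and 1 in Smad4KO (0.658), and of 13 fibroblast genes 3 rose and 1 fell in EgfrKO (0.866). Of 3 erythroid genes 1 rose in Klf5KO (0.426, 0.732 and 0.826), and of 3 adipocyte and muscle genes 1 rose in EgfrKO and 1 fell in Klf5KO (0.605, 0.217 and 0.846). B cell, keratinocyte, acinar and mitochondrial lists had too few tested genes.

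**Figure D3:**
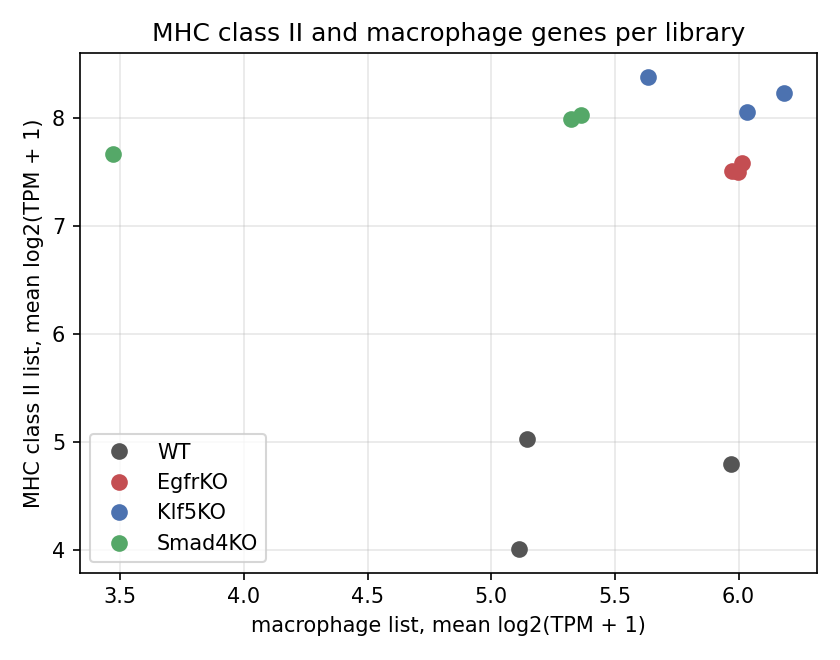
Mean log2(TPM + 1) of the 7 MHC class II genes (vertical axis) against that of the 12 macrophage genes (horizontal axis), with 1 point for each of the 12 libraries coloured by genotype label. The 3 WT libraries lie between 4.01 and 5.03 on the vertical axis and the 9 knockout libraries between 7.49 and 8.38, with Smad4KO replicate 2 at 3.47 on the horizontal axis.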

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

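The tests in this part were chosen after the results were seen, and the groups of 3 libraries are too small for a test of single libraries. Lists were set apart here where camera called them in opposite directions in 2 knockouts against WT and also called the difference between those knockouts. Epithelial identity genes differed between the Klf5KO-labelled libraries and Smad4KO by a median of -0.75 on the log2 scale, and classical and gastric-like genes by -1.99. Classical and gastric-like genes differed between EgfrKO and the Klf5KO-labelled libraries by 1.20. Camera adjusted p was 9.2e-09, 2.8e-07 and 1.3e-06, and with an estimated correlation adjusted p was 0.319 for each. The camera p-values were part of the rule that set the lists apart, so they add no evidence. The classical and gastric-like list had a median of only -0.15 in the Klf5KO-labelled libraries against WT. Its call there was lost after median-of-ratios scaling and after quantile normalization.

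Scaling of the TPM values was argued against as the whole cause of the difference between the Klf5KO-labelled libraries and Smad4KO: under 3 other scalings the median difference nearest 0 in either list was -0.77, beyond the bound of -0.5 that was set. Fewer tumour cells in the Klf5KO-labelled libraries would lower all 33 members of the 2 lists by about the same factor in TPM. The bound set for the interquartile range of their log2 fold changes was 0.27, which is 2 times their median SE. That range was 1.06, and 0.85 to 1.20 with 1 library left out, and a first bound of 1 was not met without Klf5KO replicate 1 (0.85). On the log2(TPM + 1) scale, members with low TPM fall by less for the same factor, so the range alone cannot decide. Members with like, high TPM in WT differed too. Log2 fold changes were -0.69 for Spint2 (328 to 371 TPM in WT) and -2.17 for Tff2 (259 to 461). They were 0.63 for Vsig1 (65.2 to 72.7) and -3.39 for Krt7 (58.0 to 63.8). For these members this argues against fewer tumour cells as the whole cause, if only tumour cells express them. Of the 33 members 5 were higher than WT after median-of-ratios scaling and 18 lower. Fewer tumour cells alone would not raise the 5 if only tumour cells express them. Fibroblast genes were higher in the Klf5KO-labelled libraries, but 12 of 16 mesenchymal genes rose there too, with 2 lower. Whether these transcripts came from fibroblasts or from the tumour cells cannot be told from these values. A lower share of tumour cells as part of the change and the knockout itself stay open and were not tested separately.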

How the results depend on the processing

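Of 253 results for named genes, 217 kept their direction and their side of the threshold under every alternative run on them that held the gene. Of 43 calls on gene lists 0 did, since an estimated correlation ended each one, and the cause of other changes was not tested. Most named genes were picked for a large change or a small adjusted p in these data, so their share does not describe the other genes. The fit of the 2 groups compared and the minimum fold change were run on gene counts and not on named genes. Read depth is unknown and sets no limit that can be given. The 3 alternatives with small RNA models or ribosomal protein genes left out or the macrophage covariate were chosen after seeing the data.

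Median-of-ratios scaling gave 2788 genes higher and 2721 lower in EgfrKO and 3695 and 3477 in Klf5KO against WT. Quantile normalization gave 2510 and 2766, and 3685 and 3151, with 1586 shared by the 3 knockouts. Between EgfrKO and Smad4KO, array weights gave 6871 genes, the leukocyte covariate 1996 and the macrophage covariate 2902. The fibroblast covariate, which differs between the groups, gave 889 higher and 348 lower in Klf5KO, 2838 between EgfrKO and Klf5KO, 2758 between EgfrKO and Smad4KO, 2168 between Klf5KO and Smad4KO, and 400 shared. With it Cxcl1 turned to -0.078 and Cxcl10 to 0.21 between EgfrKO and Klf5KO, and Cxcl1 to 0.72 between Klf5KO and Smad4KO. A log2 fold change of at least 1 left 448 higher and 280 lower in EgfrKO, 772 and 340 in Klf5KO, 739 and 470 in Smad4KO, 811, 637 and 1705 between knockouts in the order EgfrKO and Klf5KO, EgfrKO and Smad4KO, Klf5KO and Smad4KO, 2021 for any genotype and 240 shared, by construction. Leaving out 1 library gave 3142 to 4300 higher in EgfrKO, 6933 to 7230 in Klf5KO and 3666 to 4183 in Smad4KO, with 1677 to 2358 shared.

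The replicate numbers shared by the groups did not pair the libraries: deviations of libraries with the same number correlated at -0.15 to 0.12, 1 of 18 pairs was above 0.1, and 3 of 12 libraries correlated best with their own number. A replicate block gave 4211 higher and 1586 lower in EgfrKO, 7493 and 1515 in Klf5KO, and 4338 and 2289 in Smad4KO, and changed 2 of 253 calls on named genes, Klf5 in Klf5KO (adjusted p = 0.0556) and Lyz2 in Smad4KO (0.0786), and 0 of 43 on lists.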

Other observations

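The gene families described first, their tests, and the tests of explanations were chosen after the data were seen, and the counts of other splits of the libraries were planned before. All 16 interferon-inducible GTPase genes tested rose in each knockout, as measured and after median-of-ratios scaling, with medians of 2.45, 2.95 and 2.40 in EgfrKO, Klf5KO and Smad4KO, and Iigp1 rose from 57.0 TPM in WT to 289, 503 and 360 TPM. These genes lie in clusters of near copies, so their single values are uncertain where reads are shared. Camera adjusted p was 6.4e-11, 4.5e-07 and 3.0e-09, and 0.255, 0.324 and 0.266 with an estimated correlation. Of 19 glutathione S-transferase genes 17 rose in Smad4KO and 9 fell and 3 rose in the Klf5KO-labelled libraries, with Gsta4 at 284 TPM in WT, 1209 in Smad4KO and 68.2 in the Klf5KO-labelled libraries. After scaling none rose and 13 fell in the latter. Of 22 collagen genes 18 rose in the Klf5KO-labelled libraries, where fibroblast genes rose too, and 13 fell in Smad4KO. The 3 regenerating family genes fell in EgfrKO and in the Klf5KO-labelled libraries, and of 7 UDP-glucuronosyltransferase genes 6 rose in EgfrKO, 4 in the Klf5KO-labelled libraries and 7 in Smad4KO. With an estimated correlation the smallest adjusted p of the 8 families was 0.0756.

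MHC class II genes were higher in all 3 knockouts. More macrophages in the knockout libraries were argued against as the whole cause: the MHC class II mean minus the macrophage mean was 1.61 higher on the log2 scale in the lowest knockout library than in the highest WT library, with a range of 1.05 among the WT libraries. The same difference against general leukocyte genes was 1.72, with a WT range of 0.95, and the smallest list median under 3 other scalings was 2.89. More MHC class II transcript per leukocyte, a response of the tumour cells, and a difference in how the WT libraries were handled, where 12 of 14 immediate-early and dissociation stress genes, not always the same 12, were higher against each knockout, though the heat shock gene Hsph1 was lower than in Klf5KO, stay open and may each contribute. The genotype itself was not separated from these.

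More genes were higher than lower in the Klf5KO-labelled libraries. Leaving out ribosomal protein genes lowered the median log2 fold change of all genes from 0.31 to 0.20 (SD 0.03 over 3 libraries), which argues against their lower share as the whole cause, though part of the shift went with it. Small RNA models took 7.73% to 9.65% of TPM in the Klf5KO-labelled libraries and 7.27% to 7.96% in WT, so between a Klf5KO-labelled and a WT library their share allows a log2 shift of the other genes of at most 0.00366, against a median of 0.29 in the lowest Klf5KO-labelled library, which argues against them as the whole cause. TPM holds shares only, so whether the cells held more or less RNA stays open and no biological explanation was tested.

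Other splits of the 6 libraries of a contrast number 10 with the real one, too few for a share under 0.05. In each contrast 1 split, the real one, gave as many genes: 5920 genes against at most 4 in another split for EgfrKO against WT, 9054 against 1 for Klf5KO, 6781 against 1 for Smad4KO, 7535 against 1 for EgfrKO against Klf5KO, 4531 against 2 for EgfrKO against Smad4KO and 8716 against 1 for Klf5KO against Smad4KO. Calls on lists behaved otherwise. Camera at the preset correlation called 15 lists for EgfrKO and at most 16 in another split, 13 for Klf5KO and at most 13, and 15 for Smad4KO and at most 15, and 3, 4 and 3 of the 10 splits called as many as the real one. Of 100 splits of the 12 libraries 1, the real one, gave as many genes for any genotype, 11298 against at most 4882. A random assignment of libraries to labels thus does not explain that count. The labels do not say whether replicates came from separate tumours, so the splits cannot tell a difference between genotypes from one between tumours. For genes changed alike in 3 knockouts, 2 of 100 splits, the real one with 2389 included, gave as many, and the other gave 3472, with the 3 Klf5KO-labelled libraries in the place of WT. Few splits gave as many, but the count depends on which group serves as the common reference. It does not test sharing between the knockouts, and it cannot tell genotypes from tumours either.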
